A study of Homo sapiens with 6 samples.

How the data were processed

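RNA from the human ovarian cancer line A2780 was measured by RNA-seq in 6 libraries, 3 of the group labelled GPT2si and 3 of the group labelled GPT2sinc, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was selected for poly(A) tails with oligo(dT) beads, broken into short fragments, copied with dUTP in the second strand so that strand was kept, and amplified by PCR. The authors deposited a table of whole-number counts per Ensembl gene, not normalized, with 1 column per library. CASAVA and StringTie are named, per the submitters' processing notes, without versions or roles. The aligner, the program that made the counts, its strand setting, the genome build and the annotation release are not given in the sources used here. Each of the 6 columns was matched to its library by name, and 0 columns were left unmapped.

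The table holds 60564 gene rows, all with an Ensembl identifier. Symbols were found for 60295 of them in the gene name table used here, and 58457 occur in GENCODE 29 on GRCh38, which served only for gene types, the position of GPT2, GC content, transcript length and 3′ untranslated regions. Genes with a count above 0 in any library numbered 28550. Total counts were 43351984, 45508530 and 43691699 for GPT2sinc 1 to 3 and 50882329, 41931162 and 45183542 for GPT2si 1 to 3. A floor of 3 counts then equals 0.0590 to 0.0715 CPM. PCR reads without molecular identifiers are not independent molecules, and such floors cover counting error only.

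Differences between the groups were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on the deposited counts, with TMM factors, the filterByExpr filter and the group as the only term in the fit. Adjusted p-values are Benjamini-Hochberg values over the 17006 genes kept by the filter, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values of genes and of cell type markers are scaled by the TMM factors and given as mean ± SD with n = 3 per group. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over 40 lists. Each list was tested again with its correlation estimated, and with fry. The fry test asks whether the members of a list changed at all, while camera compares them with the other genes. With an estimated correlation camera also uses the few residual degrees of freedom of the 6 libraries. It then has less power, and a call can be lost without a higher correlation. Another 6 lists hold markers of other cell types and were used for levels. The symbol H2AC18 of the histone list was not matched. The share of counts from mitochondrially encoded mRNAs was compared with a two-sided exact permutation test, which with 3 against 3 libraries cannot give a p below 0.1.

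The test, the lists and the rule for the genes named were fixed before the data were examined. The rule names GPT2, and the 10 largest rises and the 10 largest falls among protein-coding genes past the test. These genes need a gene symbol that is not a clone name, a mean of at least 5 CPM and groups that do not overlap. From the same genes it takes the 5 with the smallest p. From each list with any member past the test it takes up to 4 members with the smallest p, whether or not they passed. From a list with none it takes the 2 most abundant members. The rule also takes the members of the list of alanine, glutamate and glutamine enzymes, and up to 4 markers of each other cell type. It took 130 genes, of which 43 passed the test; some of these genes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

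Alternatives fixed beforehand were DESeq2 size factors and upper-quartile factors in edgeR, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a block by replicate number, and leaving out each library in turn. An alternative chosen after seeing the data gave each gene and library an offset from a loess fit (span 0.5) of log2 ratios on GC content and transcript length in the edgeR fit; it covered 98.9% of the tested genes.

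No libraries were found to be duplicates: over genes, the chi-square per degree of freedom between pairs of libraries was at least 8.23, where sampling noise alone gives about 1. The labels do not state whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

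The test was checked on simulated counts drawn for GPT2si against GPT2sinc over 16731 genes, in 3 simulations with 200 changed genes each. It recovered 32.8% of genes changed 1.5-fold, 79.6% of those changed 2-fold and 100% of those changed 4-fold, and 7.22% of its calls were false. These counts were drawn independently for each gene and without GC trends of single libraries, so the shares may differ in the real data. In 50 simulations of lists, camera found 100% of lists shifted by 0.4 on the log2 scale and called 0% of unshifted lists of independent genes. The exact tests, the 3′ untranslated region search and the plots used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.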

Results

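Gene counts were measured in A2780, a human ovarian cancer cell line, in 3 libraries labelled GPT2si and 3 labelled GPT2sinc. GPT2 encodes the mitochondrial alanine aminotransferase, which converts pyruvate and glutamate to alanine and alpha-ketoglutarate and back. The series title concerns a lack of GPT2 in ovarian cancer cells, and the labels do not spell out what si and sinc stand for. Total counts ran from 43351984 to 45508530 in the GPT2sinc libraries and from 41931162 to 50882329 in the GPT2si libraries.

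The targeted gene was lower in each GPT2si library than in each GPT2sinc library. GPT2 (ENSG00000166123; chromosome 16, 46884378 to 46931297 on the plus strand of GRCh38 in GENCODE 29; protein coding) had 4714, 3677 and 4416 counts in the GPT2si libraries and 10807, 10683 and 9516 in the GPT2sinc libraries. Its level was 95.0 ± 1.69 CPM against 228 ± 8.59 CPM (SD, n = 3 each), which left 41.7% of the GPT2sinc level. The log2 fold change was −1.26 (SE 0.08; adjusted p = 0.000393, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and no other tested gene had a smaller p.

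Beyond GPT2, the lists of hypoxia response and glycolysis genes were lower with GPT2si by camera with a preset correlation, and the lists of ribosome biogenesis and MYC target genes and of MAPK feedback and immediate early genes were higher. None of these list calls held with an estimated correlation (camera adjusted p = 0.381, 0.256, 0.343 and 0.192). The estimated correlations of the hypoxia, glycolysis and ribosome biogenesis lists were 0.66, 0.14 and 0.22, far above the preset 0.01. For them the preset understates how far members move together, and a higher correlation may be part of why the calls were lost. The estimated correlation of the MAPK list was −0.00214, below the preset, so a higher correlation is not why its call was lost. By fry, which does not compare a list with other genes, the hypoxia, glycolysis, ribosome biogenesis and MAPK lists passed (adjusted p = 0.0224, 0.00623, 0.0224 and 0.00209). A pass by fry therefore does not restore the camera calls. CA9, a carbonic anhydrase of the cell surface induced by low oxygen, fell from 109 ± 5.67 to 48.1 ± 9.65 CPM (log2 fold change −1.18, SE 0.14). TAGLN, the actin-binding protein transgelin, rose from 106 ± 9.43 to 238 ± 39.0 CPM (1.17, SE 0.13). ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors, both rose by 1.15 on the log2 scale (SE 0.12 and 0.14). MAT2A, which makes S-adenosylmethionine, rose from 97.2 ± 7.19 to 175 ± 9.05 CPM (0.84, SE 0.09).

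In all, 98 genes were higher and 143 lower with GPT2si among 17006 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), of which 20 were at least 2-fold higher and 30 at least 2-fold lower. Of these 241 genes, 217 are protein coding, and in each of the 241 the GPT2si libraries all lay on the same side of the GPT2sinc libraries. Such separation was seen for 28.2% of the tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 3332 genes. Higher and lower counts were 3 and 1 without GPT2sinc 1, 0 and 1 without GPT2sinc 2, 1 and 4 without GPT2sinc 3, 1 and 1 without GPT2si 1, 377 and 459 without GPT2si 2, and 51 and 58 without GPT2si 3. Of the 43 genes past the test that the fixed naming rule took, only GPT2 stayed past it in each of these fits. They were also 569 and 491 with DESeq2, 17 and 27 with no low-count filter, and 1072 and 1135 with GC and length offsets, an alternative chosen after seeing the data.

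**Figure D1:**
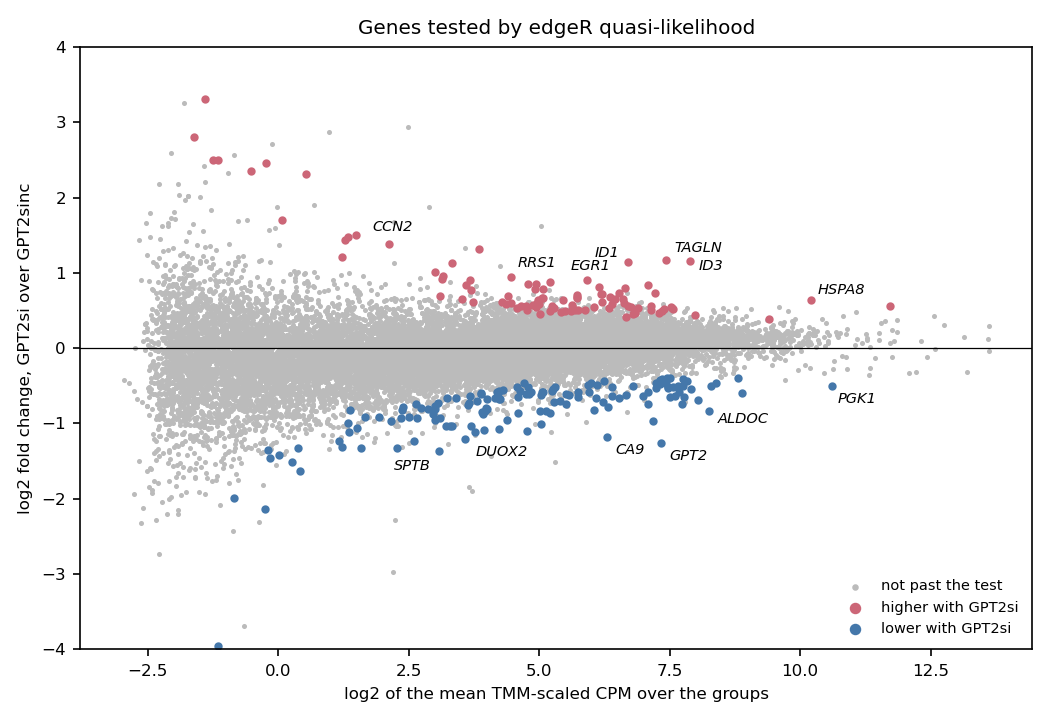
Log2 fold change of GPT2si over GPT2sinc (vertical axis) against the log2 of the mean TMM-scaled CPM (horizontal axis) for the genes tested, 1 point per gene. Red points are the 98 genes that were higher and blue points the 143 that were lower past the edgeR test; 5 genes with a change beyond 4, of which 2 passed the test, lie outside the plot.

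Among protein-coding genes with a symbol that passed the test, had a mean of at least 5 CPM and did not overlap between the groups, the largest falls besides GPT2 and CA9 included those of SPTB, a beta spectrin of the membrane skeleton (log2 fold change −1.37, SE 0.20), and of DUOX2, an oxidase that makes hydrogen peroxide (−1.21, SE 0.20). ATP1B2, a subunit gene of the sodium pump, fell as well (−1.03, SE 0.14). So did CA5B, a mitochondrial carbonic anhydrase (−1.04, SE 0.17), CPNE5, a copine (−1.04, SE 0.17), and P2RX3, an ATP-gated ion channel (−1.03, SE 0.18). UPK1A, a uroplakin, fell by 1.10 on the log2 scale (SE 0.12), but it overlaps the antisense gene UPK1A-AS1, and without a stated strand setting the reads of the pair cannot be told apart. By the same limits, the largest rises after TAGLN, ID1 and ID3 were those of ACTG2, a smooth muscle actin (1.13, SE 0.18), SERPINB8, a serine protease inhibitor (1.01, SE 0.14), and BSN, a presynaptic scaffold (0.96, SE 0.13). They were followed by RRS1, a ribosome assembly factor (0.94, SE 0.13), EGR1 and CCN1 (both 0.90, SE 0.10 and 0.14) and ID2 (0.88, SE 0.11). ENSG00000285816, a protein-coding gene with no symbol, passed the test with a larger rise (1.31, SE 0.25), but it overlaps other genes on its strand and its counts are uncertain. Larger fitted changes at this level of expression, up to 6.09, did not pass. Adjusted p of the genes with symbols by edgeR with Benjamini-Hochberg adjustment ran from 0.0111 for UPK1A to 0.0352 for P2RX3.

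Of 25 tested genes of the hypoxia response, 9 fell and 0 rose, and all 25 had a negative log2 fold change, with a median of −0.69. CA9 and ANGPTL4, a secreted inhibitor of lipoprotein lipase (−0.97, SE 0.11), fell. ALDOC, an aldolase of glycolysis, fell from 392 ± 21.2 to 220.2 ± 16.8 CPM (−0.83, SE 0.09), and PFKFB4, which sets the level of an activator of phosphofructokinase, from 326 ± 13 to 202 ± 16.4 CPM (−0.69, SE 0.09). Adjusted over the list alone, all 25 fell. Of 23 glycolysis genes, 8 fell and 0 rose (18 fell adjusted over the list alone), with a median of −0.32, among them the lactate exporter SLC16A3 (−0.74, SE 0.09) and the glucose transporter SLC2A1 (−0.44, SE 0.07). The lists share 6 tested members, ALDOC and PFKFB4 included. By camera with a preset correlation the lists were lower with adjusted p = 3.80e-14 and 2.26e-09; neither call held with an estimated correlation (adjusted p = 0.381 and 0.256 with an estimated correlation). Centred on the mean of the 6 libraries, the median of the hypoxia list was −0.59 in GPT2si 2, −0.17 and −0.18 in GPT2si 1 and 3, and 0.41, 0.29 and 0.21 in the GPT2sinc libraries.

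**Figure D2:**
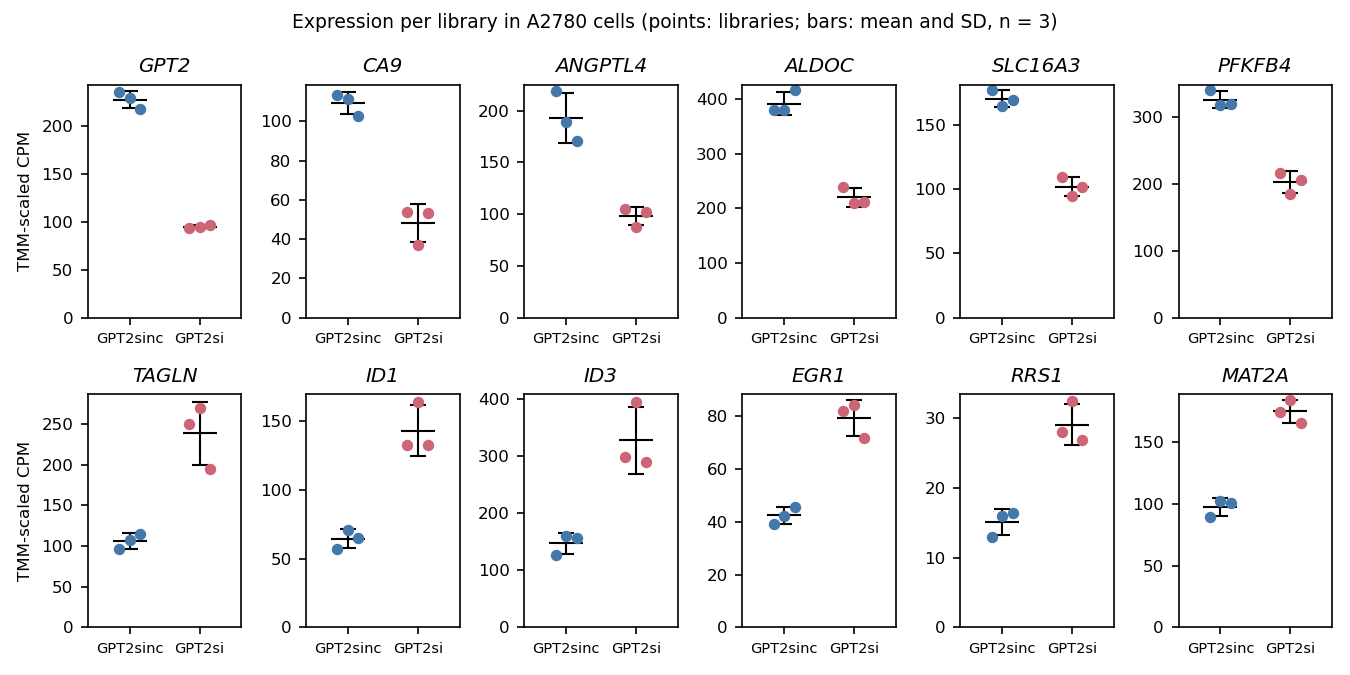
TMM-scaled CPM (vertical axes, starting at 0) of 12 genes in the 3 GPT2sinc (blue) and 3 GPT2si (red) libraries, with the mean and SD of each group as black bars. GPT2 and 5 genes of the hypoxia and glycolysis lists are lower in each GPT2si library (CA9 48.1 ± 9.65 against 109 ± 5.67 CPM), and the 6 genes of the lower panels are higher.

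Some genes that respond to extracellular signals and to cell tension rose. Of 28 MAPK feedback and immediate early genes, 5 rose and 0 fell (15 rose and 1 fell adjusted over the list alone), with a median of 0.35. They included the transcription factor genes EGR1, from 42.4 ± 3.27 to 79.2 ± 6.66 CPM, FOSL1 (0.78, SE 0.11) and EGR3 (1.21, SE 0.18), and the feedback inhibitor SPRY4 (0.56, SE 0.08). Of 19 TGF-beta targets, 4 rose and 0 fell (7 rose adjusted over the list alone): ID1, ID2, ID3 and CCN2. The ID genes are also direct targets of BMP signalling. Of 20 YAP and TEAD targets, 3 rose and 0 fell (6 rose adjusted over the list alone), namely the matricellular genes CCN2 (1.39, SE 0.17) and CCN1 and the angiomotin family member AMOTL2 (0.71, SE 0.09). By camera these lists were higher with adjusted p = 2.88e-06, 0.000872 and 0.00255, and with an estimated correlation adjusted p = 0.192, 0.256 and 0.343. The centred medians of the YAP and TEAD list overlapped between the groups, with GPT2si 2 at −0.02 and GPT2sinc 1 at 0.03. Of 21 mesenchymal genes, TAGLN and the smooth muscle actin gene ACTA2 rose (ACTA2 0.80, SE 0.09) and 19 did not pass (3 rose adjusted over the list alone); the list did not pass camera (adjusted p = 0.120). ACTA2 and ACTG2 have nearly the same coding sequence, and how the counting treated shared reads is not given in the sources used here.

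Some genes of ribosome assembly rose as well. Of 33 ribosome biogenesis and MYC target genes, 6 rose and 0 fell (22 rose and 1 fell adjusted over the list alone), with a median of 0.41. RRS1 rose from 15.2 ± 1.88 to 29.1 ± 2.99 CPM, and MRTO4, which acts in assembly of the large subunit, rose by 0.72 (SE 0.11), the box C/D snoRNP core gene NOP56 by 0.55 (SE 0.10) and POLR1A, the largest subunit of RNA polymerase I, by 0.52 (SE 0.10) on the log2 scale. CTPS1, which makes CTP, rose (0.65, SE 0.11) as the only one of 21 genes of pyrimidine and purine synthesis over all genes tested (8 rose adjusted over the list alone), and FARSB as the only one of 20 cytosolic tRNA synthetases (0.48, SE 0.10; 1 rose adjusted over the list alone). The lists were higher by camera with adjusted p = 1.28e-09, 0.00226 and 0.0179, and with an estimated correlation adjusted p = 0.343, 0.393 and 0.585. The tRNA synthetases did not pass camera without GPT2sinc 1 or without GPT2si 1.

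Heat shock genes and p53 targets rose in part. Of 18 heat shock genes 2 rose and 0 fell (7 rose adjusted over the list alone). HSPA8, the constitutive HSC70 chaperone, rose from 934 ± 106 to 1448 ± 85.5 CPM (0.63, SE 0.10), and HSPA1B rose by 0.44 (SE 0.09). The sequence of HSPA1B is nearly the same as that of HSPA1A (0.43, SE 0.09, adjusted p = 0.0509, edgeR), so that their separate values are uncertain. Of 27 p53 targets 2 rose and 0 fell (9 rose adjusted over the list alone), the exonuclease gene AEN (0.59, SE 0.11) and the kinase gene PLK2 (0.77, SE 0.15). By camera both lists were higher, with adjusted p = 8.46e-05 and 7.47e-05, and with an estimated correlation adjusted p = 0.374 and 0.256.

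Several lists passed camera although 0 of their members passed edgeR. The median was 0.23 for 58 mitochondrial ribosomal proteins (22 higher at an unadjusted p under 0.05, 5 with DESeq2, 0 adjusted over the list alone). It was 0.17 for 70 cytosolic ribosomal proteins (7, 0 and 0) and 0.11 for 72 nuclear-encoded subunits of oxidative phosphorylation (11, 1 and 0, with 1 lower at an unadjusted p under 0.05). Mitochondrially encoded mRNAs had a median of 0.34 over 13 members (7, 3 and 7) and DNA replication genes one of 0.22 over 46 (19, 8 and 10). Replication-dependent histones had 0.12 over 24 (5, 2 and 2) and cholesterol synthesis genes 0.13 over 24 (5, 3 and 3, with 1 lower at an unadjusted p under 0.05). Examples were the mitochondrial ribosomal gene MRPS27 (0.34, SE 0.09) and the replicative helicase gene MCM7 (0.50, SE 0.12). In the opposite direction, 42 mitosis genes had a median of −0.25, with 17 lower at an unadjusted p under 0.05, 7 with DESeq2 and 3 adjusted over the list alone. MKI67, the antigen of proliferating cells, was at 266 ± 43.2 against 310.4 ± 9.12 CPM. These 8 lists had camera adjusted p between 4.29e-09 and 0.0380; with an estimated correlation adjusted p lay between 0.343 and 0.647. The libraries GPT2sinc 1 and GPT2si 2 stood farthest apart in the lists of ribosomal and respiratory chain proteins. For mitochondrial ribosomal proteins the centred median was −0.23 and 0.24 in them, and −0.09, −0.02, 0.08 and 0.01 in GPT2sinc 2, GPT2sinc 3, GPT2si 1 and GPT2si 3. For subunits of oxidative phosphorylation it was −0.20 and 0.21 in them, 0.02 in GPT2si 1 and −0.03 in GPT2si 3, with GPT2sinc 3 at 0.03. For cytosolic ribosomal proteins the groups overlapped as well, with GPT2si 3 at −0.01 and GPT2sinc 3 at 0.00. For mitochondrially encoded mRNAs it was GPT2sinc 2 at −0.40 and GPT2si 2 at 0.37 that stood apart, with the other libraries between −0.07 and 0.06. For mitosis genes GPT2si 2 lay at −0.31 and GPT2si 1 and 3 at −0.09 and −0.06. The GPT2sinc libraries then lay at 0.12, 0.10 and 0.16. For DNA replication genes GPT2sinc 1 lay at −0.22, GPT2sinc 2 and 3 at −0.05 each, and GPT2si 1 to 3 at 0.11, 0.17 and 0.06. Without GPT2sinc 1 or GPT2si 2 the subunits of oxidative phosphorylation and the histones did not pass camera, and cholesterol synthesis did not pass without GPT2sinc 1, 2 or 3. With GC and length trends removed, an alternative chosen after seeing the data, the histones did not pass either (median 0.04, camera adjusted p = 0.241).

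**Figure D3:**
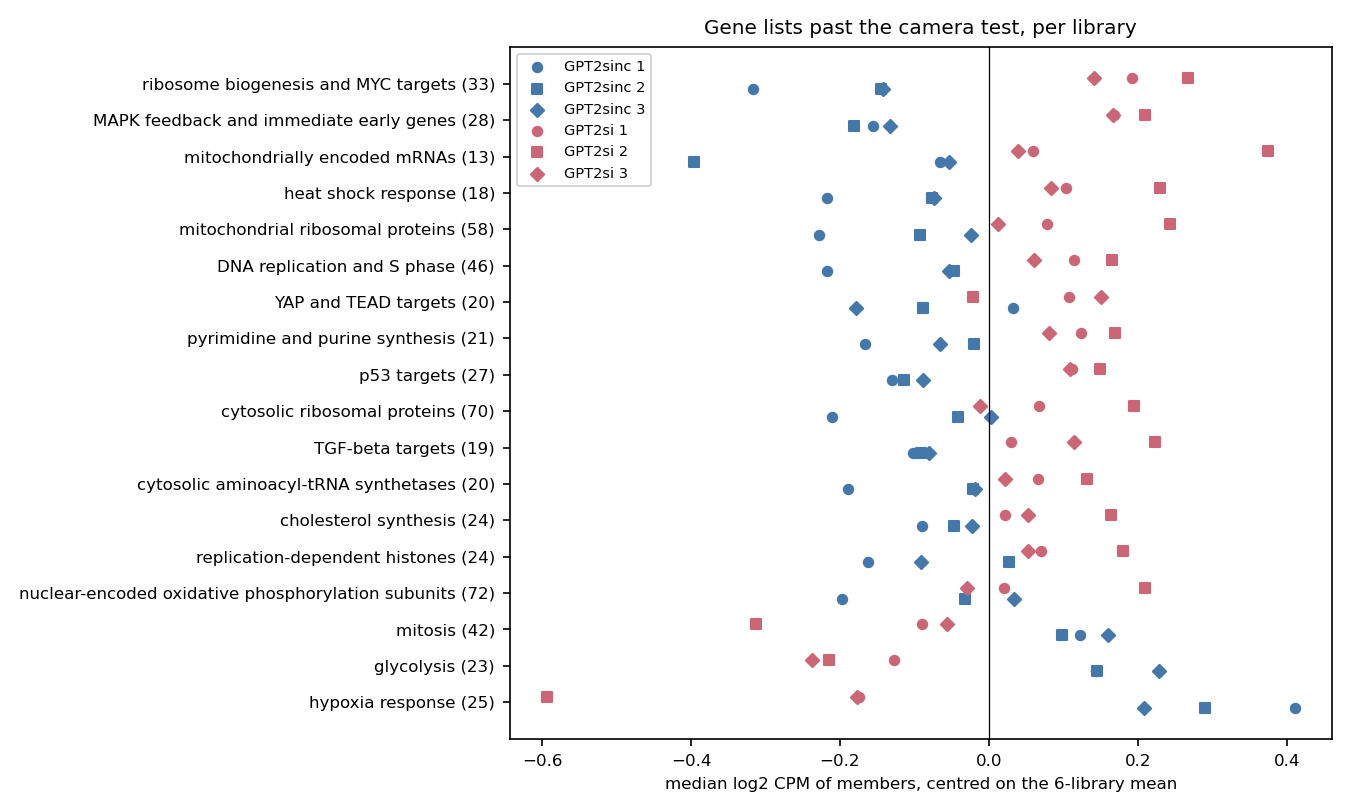
Median log2 CPM of the members of each of the 18 gene lists past camera with a preset correlation, each member centred on its mean over the 6 libraries (horizontal axis), with the tested members in brackets. Blue marks are GPT2sinc and red marks GPT2si libraries, with a circle, square and diamond for replicates 1, 2 and 3; the GPT2si 2 square lies at −0.59 for the hypoxia response.

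Besides GPT2, no gene of alanine, glutamate and glutamine metabolism passed the edgeR test. Of 18 tested members 17 did not pass, the list as a whole did not pass camera (adjusted p = 0.504), and adjusted over the list alone 1 fell. By fry the list, which includes GPT2 itself, passed (adjusted p = 0.0224). At an unadjusted p under 0.05, 1 member was higher and 3 were lower, GPT2 included, and with DESeq2 0 were higher and 2 lower, GPT2 and ABAT. ABAT passed with DESeq2 (adjusted p = 0.0419) and with GC and length offsets in edgeR (adjusted p = 0.0162, the lowest of its alternatives, up to 0.368). BCAT2 passed with these offsets alone (adjusted p = 0.0456, against up to 0.894 in other alternatives). The cytosolic paralog GPT was at 2.04 ± 0.59 against 2.58 ± 0.52 CPM (−0.35, SE 0.26). The aspartate aminotransferases GOT1 and GOT2 were at 0.22 each (SE 0.10 and 0.11), GLS2 at 0.22 (SE 0.17), glutamine synthetase GLUL at 0.16 (SE 0.09), and glutamate dehydrogenases GLUD1 and GLUD2, which are nearly the same in sequence, at −0.05 and −0.02 (SE 0.08 and 0.14). The transaminases PSAT1, BCAT1, BCAT2, OAT, KYAT1 and KYAT3 lay between −0.24 for BCAT1 and 0.00 for PSAT1, asparagine synthetase ASNS at 0.12 (SE 0.09), and the GABA enzymes ABAT at −0.34 (SE 0.10) and GAD1 at −0.93 (SE 0.32, at 2.55 ± 0.50 against 4.87 ± 2.48 CPM). In the main edgeR fit, adjusted p of these members ran from 0.124 for ABAT to 0.988 for PSAT1.

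Other amino acid genes moved little as groups. Of 38 ATF4 amino acid response genes, 1 fell and 0 rose: STC2, a secreted glycoprotein also induced by low oxygen (−0.65, SE 0.12; adjusted over the list alone 1 rose and 1 fell). TRIB3, a pseudokinase of that response, was at 0.40 (SE 0.11) and the stress cytokine gene GDF15 at 0.49 (SE 0.15), neither past the test. In serine and one-carbon metabolism MAT2A alone of 18 genes rose, also when adjusted over the list alone. Of 23 amino acid transporters 0 passed edgeR (9 higher and 4 lower at an unadjusted p under 0.05, 3 and 1 with DESeq2, 6 and 3 adjusted over the list alone), with SLC7A5 at 0.37 (SE 0.11) and SLC1A5 at 0.38 (SE 0.12). Camera gave adjusted p = 0.169, 0.242 and 0.365 for these lists.

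Of 32 apoptosis regulators CASP2 rose (0.51, SE 0.10; 1 rose and 1 fell adjusted over the list alone). For TCA cycle and pyruvate entry, 0 of 32 genes passed (1 higher and 4 lower at an unadjusted p under 0.05, 0 and 2 with DESeq2, 0 and 2 adjusted over the list alone), with IDH2 at −0.14 (SE 0.10). For fatty acid synthesis it was 0 of 18 (3 and 1, 1 and 1, 1 and 0), where FASN was at 0.54 (SE 0.12) and the desaturase SCD at −0.28 (SE 0.08), and for fatty acid oxidation 0 of 20 (2 and 2, 0 and 1, 0 and 0). Among 24 glutathione and NRF2 targets and 24 ferroptosis regulators 0 passed (2 and 3 higher and 1 each lower at an unadjusted p under 0.05, 1 and 3 higher with DESeq2, 0 and 2 adjusted over the list alone). The ferritin genes FTH1 and FTL, which have processed copies elsewhere in the genome, were at 0.21 and 0.16 (SE 0.10 and 0.11). Among 24 genes of the unfolded protein response 0 passed (1 higher and 4 lower at an unadjusted p under 0.05, 0 with DESeq2, 0 adjusted over the list alone), with the chaperone gene HSPA5 at −0.22 (SE 0.08). The remaining 10 lists held 0 members past edgeR: interferon-stimulated genes, NF-kappaB genes, autophagy and lysosome, collagens and matrix, epithelial markers, drug efflux and platinum response, homologous recombination, and Wnt, Notch and Hedgehog targets. Each of them had 2 to 7 members higher and 0 to 5 lower at an unadjusted p under 0.05, 0 to 2 either way with DESeq2, and 0 to 3 higher and 0 to 2 lower adjusted over the list alone. Camera adjusted p of the 22 lists not past the test ran from 0.120 to 0.961.

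Mitochondrially encoded mRNAs took 4.64 ± 0.38% of counts with GPT2si and 4.02 ± 0.59% with GPT2sinc (SD, n = 3 each; two-sided exact permutation p = 0.3, smallest possible 0.1). The most abundant was MT-CO1, with a log2 fold change of 0.29 (SE 0.14) that did not pass the test.

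Markers of other cell types were mostly low. The leukocyte marker CORO1A was at 33.3 ± 3.87 against 40.2 ± 1.58 CPM, CD68 at 5.75 ± 2.05 against 4.62 ± 0.62 CPM and CD53 at 1.64 ± 0.08 against 1.38 ± 0.25 CPM. The endothelial marker EGFL7 was at 30.2 ± 4.4 against 32.5 ± 1.71 CPM, the squamous marker SFN at 18 ± 2.71 against 19.6 ± 2.84 CPM, and the erythroid and hepatocyte markers HBA1, HBA2 and FGB were under 1 CPM. Fibroblast markers were abundant in both groups, with COL3A1 at 2587 ± 105 against 2561 ± 65.9 CPM (0.01, SE 0.08).

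On the first principal component of log2 CPM, which held 40.2% of the variance, GPT2si 2 lay at 56.2 and GPT2sinc 1 at −39.6, with the other libraries between −15.9 and 10.8. The library GPT2si 2 differed from GPT2si 1 and GPT2si 3 with a chi-square per degree of freedom of 41.4 and 50.8, against 8.23 between those. Across genes, which are not independent replicates, the Spearman correlation of a library's log2 ratio with GC content was 0.68 in GPT2si 2, −0.54 in GPT2si 3, −0.25 in GPT2si 1, and −0.39, −0.14 and 0.03 in GPT2sinc 1, 2 and 3.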

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

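The fits with GC and length offsets were chosen only after the result was seen; all other settings were fixed before the data were examined. GPT2 stayed lower and past the threshold under each of the 14 settings, with log2 fold changes from −1.33 to −1.24 and adjusted p from 1.65e-39 to 0.0189 (edgeR, DESeq2 or limma-voom). Under each setting all of the 241 genes that were tested in it kept their direction. The groups do not overlap in any of the 241, so leaving out 1 library could hardly reverse a direction, and this adds no support. The counts of genes higher and lower were 61 and 112 with DESeq2 size factors, 75 and 167 with upper-quartile factors, 17 and 27 with no low-count filter, 569 and 491 with DESeq2, and 1072 and 1135 with GC and length offsets. At least 2-fold higher and lower were 7 and 9 with no filter, 13 and 29 with at least 1 CPM in at least 3 libraries, 18 and 57 with DESeq2, and 36 and 122 with the offsets. Leaving out 1 library gave from 0 to 377 genes higher, 1 to 459 lower, 0 to 24 at least 2-fold higher and 1 to 37 at least 2-fold lower. Fewer libraries, and with no filter more genes tested (28550), may be part of the cause of lower counts. Without GPT2si 2, however, 377 genes were higher and 459 lower, so the counts also depended on which library was left out. No cause was tested. Lists past camera were 15 higher and 3 lower. They were 0 and 0 with an estimated correlation, where 4 passed at an unadjusted p under 0.05 and the smallest adjusted p was 0.192. The fry test called 11 and 4, of which 12 were among the 18. The others were the lists of mesenchymal genes, ferroptosis regulators and alanine, glutamate and glutamine enzymes, with adjusted p = 0.0224 each by fry. Without any 1 library 14 to 18 of the 18 list calls were kept, and 17 with GC and length trends removed. The mean mitochondrially encoded share of counts stayed higher with GPT2si in each setting, by 0.295 to 0.874 percentage points. The groups overlapped, however, with GPT2sinc 1 at 4.54% above GPT2si 1 at 4.37% and GPT2si 3 at 4.46%. In simulated counts 32.8% of changes of 1.5-fold were found, so many such changes may pass unseen. The simulation drew genes independently and without the GC trends of single libraries, so recovery in these data may differ.

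With a replicate block, 252 genes were higher and 306 lower, of which 39 were at least 2-fold higher and 76 at least 2-fold lower, and 236 of the 241 genes passed; the same 18 lists passed. The deviations of libraries with the same number correlated with r = 0.09, 0.11 and −0.19, and not every library correlated best with its own number. These few correlations do not settle whether the numbers pair the libraries.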

Other observations

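The tests of lists in this part, the separate tests of ribosomal and respiratory chain lists for GC trends, the test of culture state and the splits with GC and length offsets were chosen only after the result was seen, as were the genes named here. Genes that rose or fell were sorted into 7 further lists by known function, so that the list values are no independent evidence. Of 29 actin cytoskeleton genes of the SRF and MRTF programme 7 rose and 0 fell, of which 4 are also in fixed lists, among them the focal adhesion gene VCL (log2 fold change 0.39, SE 0.07) and the filamin gene FLNA (0.55, SE 0.11). Of 62 ribosome biogenesis factors outside the fixed list 12 rose and 0 fell, and 59 had a positive value, including URB1 (0.61, SE 0.10) and DDX31 (0.59, SE 0.10). Of 21 snoRNA host genes 3 rose, SNHG3, SNHG15 and SNHG17, and of 12 serine and arginine-rich splicing factors 2 rose, SRSF2 and SRSF6. The medians of these lists were 0.29, 0.31, 0.24 and 0.16.

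In the other direction, 17 of 31 hypoxia genes outside the fixed hypoxia list fell and 0 rose, with a median of −0.61; 8 of the 31, of which 4 fell, are in other fixed lists. Among those that fell were HIF3A (−0.87, SE 0.12), MIR210HG, the host transcript of a microRNA induced by low oxygen (−1.08, SE 0.15), and PGK1 (−0.51, SE 0.09), which is also in the glycolysis list. Of 23 genes of branched-chain amino acid breakdown, with its regulators included, 3 fell and 0 rose. The genes that fell included BCKDHA, a subunit of the branched-chain ketoacid dehydrogenase (−0.42, SE 0.08), and BCKDK, the kinase that inhibits this enzyme (−0.64, SE 0.08). Of 21 glycogen genes 3 fell and 0 rose, namely the phosphorylase PYGM (−0.50, SE 0.08), PPP1R3C, which targets a phosphatase to glycogen (−1.01, SE 0.17), and PGM1 (−0.50, SE 0.08), which is also among the 31 hypoxia genes.

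The medians of the hypoxia and glycolysis lists were lower in each GPT2si library than in each GPT2sinc library. The GC content and transcript length trends of single libraries do not account for it, since with these trends removed the median of the hypoxia list was −0.59 (−0.65 to −0.51 without any 1 library) and that of the glycolysis list −0.37 (−0.41 to −0.35). A culture state such as oxygen or cell density could not be excluded. Libraries of the same group also differed, but the labels do not say whether they came from separate cultures. The group means of the hypoxia list median lay 0.62 apart. The largest range of that median within a group was 1.10 times the gap between the nearest libraries of the groups (0.42 against 0.38). That range came from GPT2si 2, and without it the ratio was 0.55 (0.22 against 0.39). With no measure of culture in the labels, such a state and an effect of lower GPT2 cannot be told apart, and the latter stays open as untested.

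The lists of ribosome biogenesis genes, mitochondrial ribosomal proteins, cytosolic ribosomal proteins and oxidative phosphorylation subunits were higher with GPT2si by camera with a preset correlation, but not with an estimated one (adjusted p = 0.343, 0.483, 0.628 and 0.647 with an estimated correlation). With GC content and transcript length trends removed, the median of the ribosome biogenesis list was 0.38 (0.32 to 0.41 without any 1 library) and that of the mitochondrial ribosomal list 0.18 (0.12 to 0.22), which argues against the opposite GC trends of GPT2sinc 1 and GPT2si 2 as their whole cause. The medians of the cytosolic ribosomal and oxidative phosphorylation lists were then 0.11 (0.06 to 0.14) and 0.08 (0.00 to 0.11), and both lists still passed camera with a preset correlation (adjusted p = 3.75e-06 and 0.0254). Before the trends were removed they were 0.17 and 0.11. With the trends removed, these medians still fell to 0.06 and 0.00 without GPT2si 2, so they rested in part on that library beyond the fitted trends. For these lists the trends, other differences of GPT2si 2 and an effect of lower GPT2 cannot be told apart. Such an effect was not tested apart from the group in any of the lists.

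A few short RNAs without poly(A) tails, all made by RNA polymerase III, were higher with GPT2si: RN7SL1 had 318 counts in the 3 GPT2si libraries against 65 in the 3 GPT2sinc libraries (log2 fold change 2.31, SE 0.37), RN7SL2 92 against 9 (3.32, SE 0.55) and RN7SK 189 against 35 (2.46, SE 0.37), while RMRP with 55 against 9 and RPPH1 with 47 against 10 did not pass the test. More RNA without tails carried through the oligo(dT) selection may be the cause and could not be excluded. The snoRNA and histone classes had medians of 0.26 (15 genes, quartiles 0.13 and 0.57) and 0.12 (24 genes, −0.06 and 0.40), with SNORD3A at 52 against 50 counts. By a rule fixed beforehand, medians this low in both classes count against this cause, but their upper quartiles leave it open. The 20 mitochondrial tRNA genes had a median of 0.36, where MT-TE passed the test (0.92, SE 0.15). Mitochondrially encoded mRNAs had a similar median of 0.34, so the tRNA median does not speak for this cause. Against it stand the mitochondrial rRNA genes MT-RNR1 and MT-RNR2, at −0.43 and −0.32 (SE 0.10 and 0.09, neither past the test) and lower in each GPT2si library than in each GPT2sinc library. At 665 to 5784 CPM, however, these would not show a small added share, and they do not settle the question. A rise of polymerase III transcripts as a group is a hypothesis that these few counts, from libraries selected for poly(A), do not settle.

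If si stands for a small interfering RNA against GPT2, a seed match to other transcripts may have lowered them. The 3′ untranslated regions of 130 of the 142 other genes that fell were searched for each of the 3483 different 7-base words of the longest GPT2 transcript. The most frequent word was in 42.3% of the 130 genes and in 28.8% of the tested genes. It was in 47.2% of the 142 if each gene not searched held it, so no single 7-base word lay in most of the genes that fell. The word with the largest excess was in 40.0% of the 130 genes and in 22.6% of the tested genes. Shorter seed matches and matches of the other strand of the reagent were not searched. The sequence of the reagent is not given in the sources used here, and a seed effect stays open.

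There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 241 genes past the test and the highest other 2; for genes at least 2-fold changed the values were 50 and 2, for lists past camera 18 and 9, and for genes with GC and length offsets 2207 and 1.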
